A study of Canis lupus familiaris with 20 samples.

How the data were processed

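The data were RNA-seq libraries of dog osteosarcoma cell lines and of exosomes from their culture supernatants. Per the labels' protocols, exosomes were enriched with ExoQuick, a precipitation reagent, their RNA was prepared with the SeraMir ExoRNA kit, and libraries were made with the SMARTer Stranded Total RNA-seq Kit v2 for low input. The authors deposited 1 table of whole-number read counts per gene for 24579 dog gene identifiers, and their totals differ between libraries, as raw counts do. The submitters' processing notes name FastQC 0.11.5, Trimmomatic 0.33.0 and kallisto 0.43.0, and the builds CanFam3.1 and GRCm38.p5, without their order or role. The name of the deposited table refers to Subread, while the processing notes list kallisto. Which of them made the counts, its strand setting and its treatment of reads shared between similar genes are not given in the sources used here, so counts of near-identical or overlapping genes are uncertain. No molecular identifiers are described, so confidence intervals and limits for a count of 0 cover counting error only. There was 1 column of the table that matched no sample label, headed as OSCA-78 exosome replicate 1, and it was not used.

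Libraries were grouped by fraction and line from their titles. The files do not pair identifiers with names, and 0 of the 24579 identifiers matched the RefSeq gene table at hand. The 39 gene lists fixed before the data were examined could therefore not be tested, nor could genes be left out by class. The rule for named genes asked for an adjusted p under 0.05, the same sign in all 4 lines, a mean log2 CPM of at least 3 and a symbol, ordered by fold. Without symbols it was applied to identifiers, and 2 that rose and 2 that fell are given.

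The count tests were edgeR's quasi-likelihood F test (edgeR 4.0.16, limma 3.58.1, R 4.3.3) with TMM scaling, filterByExpr (minimum count 10), robust dispersions and Benjamini-Hochberg adjustment at 0.05. Exosomes and cells were compared in one fit of 18 libraries with a coefficient for each line and fraction, from which came the mean over 4 lines, each line alone and the interaction of line and fraction. Exosomes were compared between 5 lines in a fit of 12 libraries and cells between 4 lines in a fit of 8. Genes were grouped by pooled cell CPM into 5 groups of equal size, plus those without a cell count, a grouping chosen after seeing the data. Genes detected at the lowest total were computed as the mean number under subsampling. Measures per library were compared by exact permutation tests of line means. The match of exosomes to cells used log2 CPM with a prior count of 2 and all 24 assignments of lines.

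Replicates were compared before averaging. Within each group the chi-square per degree of freedom of replicate pairs was at least 1.79, so no library was taken as a copy of another. The difference of letter A minus letter B in cells correlated between lines at 0.174 to 0.482 in 6 of 6 pairs of lines, so the letters were taken to pair the cell libraries, a pairing that comes from the data and not from the labels. Alternatives were RLE, total count and upper quartile scaling, other filters, thinning, DESeq2 1.42.0, limma voom with quality weights, the replicate block, other models and leaving out each library.

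The fits were tested on simulated counts with the dispersions and library sizes of the real libraries and 1 mean per gene, pooled over all libraries of the fit. A known fold was given to 200 genes, as many up as down. Simulated cells and exosomes thus shared 1 profile apart from those genes, whereas 12695 of 16211 genes were called in the data. The rates below hold for that simpler setting and need not carry over. For the mean of 4 lines (16211 genes), 19% of genes changed by a fold of 2, 68% of those by a fold of 4 and 90% of those by a fold of 16 were recovered. With only OS-2 exosomes changed, the interaction recovered 0%, 0% and 43% (16211 genes), and exosomes between lines 0%, 31.5% and 71.5% (15083 genes). With only OS-2 cells changed, cells between lines recovered 0%, 0.5% and 65% (14148 genes).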

Results

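RNA was sequenced from dog osteosarcoma cell lines and from exosomes, the small membrane vesicles that cells release, recovered from their culture supernatants. The study set out to find an exosomal gene signature for dogs with this bone tumour. There were 8 cell libraries, 2 each of the lines OS-1, OS-2, OSCA-78 and OSCA-8. There were 12 exosome libraries, 4 of OS-1 and 2 each of OS-2, OSCA-32, OSCA-78 and OSCA-8, so that OSCA-32 was represented by exosomes alone. Total counts ran from 7728553 to 13301840 in the cell libraries and from 259078 to 481487 in the exosome libraries. A count of 0 therefore allowed up to 0.226 to 0.388 CPM (counts scaled to the library total) in a cell library and 6.23 to 11.6 CPM in an exosome library, taking 3 counts as the limit. Nothing in the labels states that replicates came from separate cultures, so p-values measure the spread between these libraries, which may be technical, and speak for these lines only. Genes are given by their Ensembl identifiers because the files do not pair them with names.

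The first comparison asked how the RNA of exosomes differed in composition from that of the cells. Exosome samples went through precipitation with ExoQuick and a kit for exosome RNA, steps that belong to their fraction. Here and below, differences between the fractions cannot be told apart from effects of these steps. Exosome counts were spread over more genes. Between 16565 and 21281 genes were detected in the exosome libraries and between 14704 and 16273 in the cell libraries, although the cell libraries were deeper. Thinned to the total of the smallest library, cells showed 11516 ± 394 genes (SD over 4 lines) and exosomes 18809 ± 2288. Totals alone were matched here, and the counts left to other genes were not, since 1 gene took up to 32.3% of an exosome library and 10 genes up to 62.7%. The line means did not overlap (exact two-sided permutation test of 4 against 4, p = 0.0286, the smallest p this design allows). An exact sign-flip permutation test that keeps each line paired with itself could not go below p = 0.125. A set of 5768 genes had no count among the 91592873 pooled cell counts. These genes took 1.10% of the counts in OS-2 exosome replicate 2 (Clopper-Pearson 95% interval 1.07% to 1.13%) and 7.33% in OSCA-32 replicate 2 (7.25% to 7.41%), the lowest and highest exosome libraries. At the other end of the scale, a few genes dominated some exosome libraries. The 10 most abundant genes took 5.78% to 9.61% of the counts of cell libraries and 1.63% to 62.7% of those of exosome libraries. By line means, their share was 26.2 ± 23.4% in exosomes and 7.50 ± 1.46% in cells (SD, n = 4 lines, exact permutation p = 0.0571), a difference that did not pass 0.05. This share was 57.1% and 62.7% in the OS-2 exosome libraries. It lay between 1.63% and 2.82% in OS-1 replicates 3 and 4, both OSCA-32 libraries and OSCA-78 replicate 3, below all cell libraries.

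**Figure D1:**
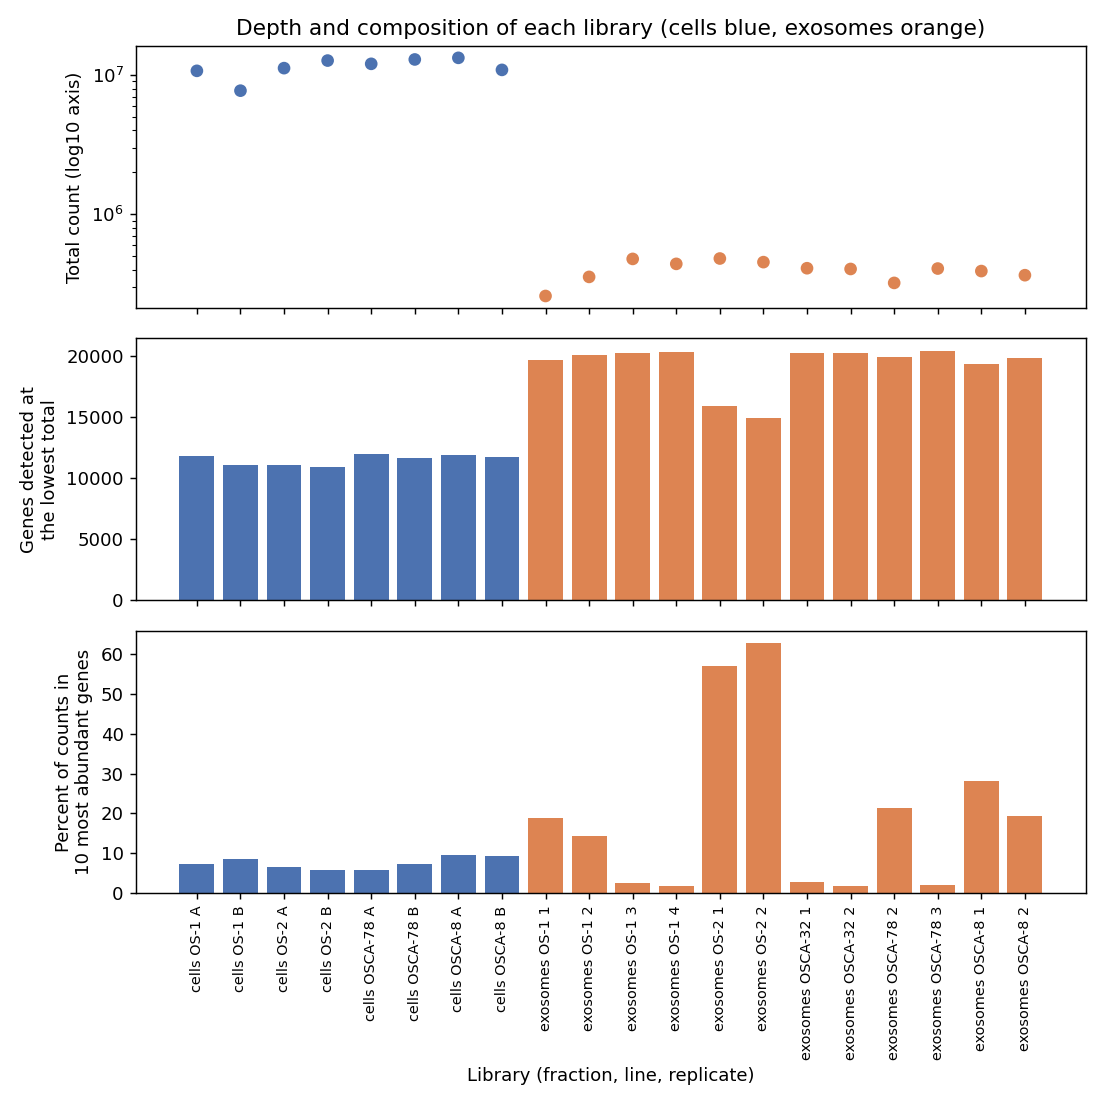
Total count (log axis), genes detected after thinning to the total of the smallest library, and percent of counts in the 10 most abundant genes, one point or bar per library, cells in blue and exosomes in orange. All exosome libraries lie above all cell libraries in genes detected at an equal total (14883 to 20403 against 10873 to 11947), while the share of the 10 most abundant genes ranges from 1.63% to 62.7% among exosomes.

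The second comparison asked which genes differed between exosomes and the cells of the same line, averaged over 4 lines. Genes that were scarce in cells took a larger part of the exosome counts, and the genes most abundant in cells a smaller part. Genes with a cell count were divided into 5 equal groups by their pooled cell CPM. Group 1, the scarcest, took 0.0207% to 0.0351% of the counts of cell libraries and 2.0% to 10.6% of those of exosome libraries, and group 2 took 0.433% to 0.703% and 10.9% to 21.3%. Group 5, the most abundant, took 78.5% to 82.5% in cell libraries and 29.9% to 64.7% in exosome libraries. Single genes carried much of the upper values, as ENSCAFG00000029369 of group 2 took 18.9% of OS-2 replicate 2 and a gene of group 5 took 32.3% of OS-2 replicate 1. Without the 7 genes over 1% of any exosome library, and as a share of the counts left, group 1 took 4.31% to 10.8% of exosome libraries, group 2 took 6.07% to 14.4% and group 5 took 29.3% to 59.1%. Group 4 then took 16.6% to 21.3% of exosome libraries and 13.1% to 15.7% of cell libraries. By gene, 56 of the 3762 tested genes of group 5 rose in exosomes and 3359 fell (edgeR, adjusted p under 0.05), and in group 4, 403 of 3761 rose and 1918 fell. These calls rest on TMM scaling, so those of group 4 do not mean a smaller share of the counts. The filter on low counts kept 1858 of the 3763 genes of group 1 and 2388 of the 3762 of group 2. It also kept 1289 of the 5768 without a cell count. Its cutoff was 20.8 CPM in 2 or more libraries, set by the totals of all 18 libraries. Of the genes kept, 0 reached it in 2 or more cell libraries. At no more than 4.23 CPM in pooled cells they could hardly do so, and the fit of cells alone had a cutoff of its own. Since these genes entered the test through their exosome counts, their calls are given without the filter. Then 2443 of 3763 genes of group 1 and 2739 of 3762 of group 2 were higher, and 25 of group 2 were lower. The direction of group 1 was fixed by the grouping, though, since its genes stood at 0.0109 to 0.251 CPM in pooled cells. That lies below the 0.629 CPM that 3 counts over the exosome libraries of the fit make. Group 2, at 0.251 to 4.23 CPM, was bound in part, since 3 counts make 6.23 to 11.6 CPM in a single exosome library. In group 3, 1174 of the 3153 tested genes reached 20.8 CPM in 2 or more cell libraries. Without the filter, 1469 of the 3762 genes of group 3 were higher and 507 lower. The median fitted log2 fold change of tested genes was -0.65 in group 4 and -1.70 in group 5. With the groups formed from the cell libraries of letter A and the fold changes taken against those of letter B, these medians were -0.37 and -1.41.

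Altogether 12695 of 16211 genes passed edgeR's quasi-likelihood test at a Benjamini-Hochberg adjusted p under 0.05, 7135 higher and 5560 lower in exosomes. The fold exceeded 2 for 6702 of those higher and 4414 of those lower. The direction was the same in all 4 lines for 6594 of the higher and 4930 of the lower genes. Of the higher genes, 1117 had no cell count, 1746 were of group 1 and 2252 of group 2, and 0 genes of these groups were lower. Their direction was fixed by their scarcity in cells, for group 2 in part. For these genes the same direction in all 4 lines therefore does not measure agreement between lines. The balance of directions depended on depth and on the scaling. With all libraries thinned to the smallest total, 7588 genes were higher and 3411 lower. With RLE scaling 8180 genes were higher and 3978 lower, with total counts 7892 and 4209, and with upper quartile scaling 8090 and 4094. The median log2 fold change of all genes was 0.38 with TMM and 0.92, 0.82 and 0.88 with those scalings. Relative to that median, group 5 genes lay at -2.08 with TMM and with each of those scalings. Scaling shifts all genes by about the same amount, so this value could hardly move with it. Without the filter on low counts it was -3.31. With RLE scaling, 875 genes of group 4 were higher and 1081 lower, and 152 and 2772 of group 5.

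**Figure D2:**
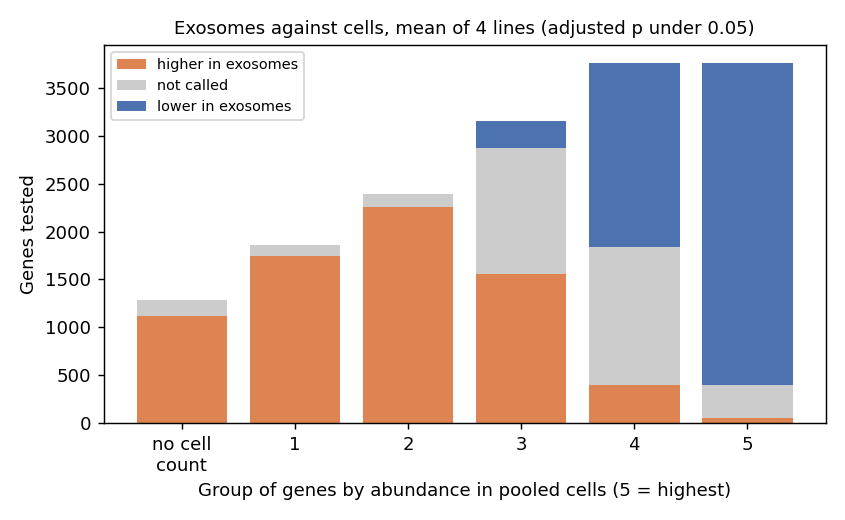
Number of genes tested (vertical axis) that were higher, lower or not called in exosomes against cells, averaged over 4 lines, for groups of genes ordered by abundance in pooled cells (horizontal axis). Lower genes make up most of the most abundant group (3359 of 3762). The bars of the scarcest groups hold the genes that passed the filter on low counts through their exosome counts (1289 of 5768 without a cell count, 1858 of 3763 in group 1 and 2388 of 3762 in group 2).

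**Figure D3:**
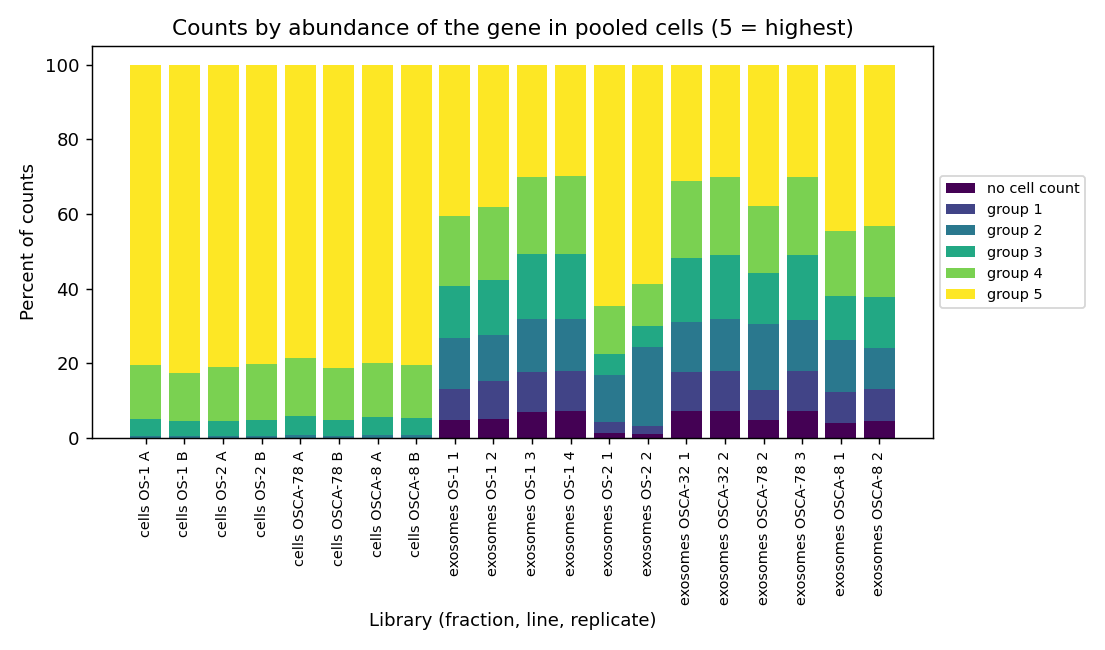
Percent of the counts of each library (vertical axis, stacked bars) that fell in genes of each cell abundance group, from no cell count to group 5. Group 5 takes 78.5% to 82.5% of each cell library and 29.9% to 64.7% of each exosome library, with the highest exosome values in OS-2, where 1 gene of group 5 alone takes 32.3% of replicate 1. Without the 7 genes over 1% of any exosome library, group 5 takes 57.2% and 59.1% of the counts left in OS-2 and 29.3% to 37.8% in the other exosome libraries.

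Among the genes that rose most, ENSCAFG00000029369 had 356 counts over all cell libraries, 346 of them in OSCA-8 replicate B, and 177526 counts over the exosome libraries of the 4 lines. Its exosome level was 143550 ± 64420 CPM in OS-2 (SD, n = 2), 33081 ± 46770 CPM in OSCA-78 (n = 2), 23266 ± 32826 CPM in OSCA-8 (n = 2) and 4915 ± 9783 CPM in OS-1 (n = 4), so that the SD exceeded the mean in 3 of these lines. In OSCA-32, outside the fit, it was 2.44 ± 3.45 CPM (n = 2), below the 3.68 CPM that 3 counts in that group make. Its fitted log2 fold change was 15.40 (SE 3.03, edgeR adjusted p = 2.65e-04). With the replicate block its fitted log2 fold change was 13.93 with an edgeR adjusted p of 1. All its cell counts of letter A were 0, but the cause was not tested. DESeq2 gave it no adjusted p. ENSCAFG00000030655 had 11 counts over all cell libraries and 21717 over the exosome libraries of the 4 lines. Its exosome level was 13532 ± 6279 CPM in OSCA-8 (n = 2), but in the other lines of the fit the SD exceeded the mean, with 4172 ± 6609 CPM in OS-1 (n = 4), 4814 ± 6600 CPM in OS-2 (n = 2) and 1656 ± 2293 CPM in OSCA-78 (n = 2). In OSCA-32, outside the fit, it was 8.58 ± 1.66 CPM (n = 2). Its fitted log2 fold change was 14.73 (SE 2.17, edgeR adjusted p = 3.39e-05). With so few cell counts, both fitted folds depend on the prior count. Among the genes that fell most by fitted fold was ENSCAFG00000005978. It stood at 254 ± 3.76 CPM in OS-2 cells and 245 ± 157 CPM in OSCA-8 cells (n = 2 each). The exosomes of these lines had no count of it. It was at least 79.1-fold lower in OS-2 exosomes and at least 61.7-fold lower in OSCA-8 exosomes, taking 3 counts per group as the limit. In OSCA-78 it stood at 325 ± 17.0 CPM in cells and 41.3 ± 51.5 CPM in exosomes (edgeR adjusted p over lines 2.07e-07). ENSCAFG00000015452 stood at 24.01 ± 0.586 CPM in OS-2 cells, 39.0 ± 11.4 in OSCA-78 cells and 39.3 ± 0.0841 in OSCA-8 cells (n = 2 each). It had no exosome count in these 3 lines and was at least 7.48-fold, 9.49-fold and 9.91-fold lower (edgeR adjusted p over lines 4.71e-08). In OS-1 it stood at 25.7 ± 11.4 CPM in cells (n = 2) and 1.41 ± 2.82 CPM in exosomes (n = 4). For ENSCAFG00000005978 the OS-1 values were 286 ± 216 and 2.50 ± 3.64 CPM. Where exosomes had no count, fitted folds depend on the prior count. The fitted log2 fold change of ENSCAFG00000015452 was -9.16, but -4.87 with limma voom and -5.55 with DESeq2.

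Within single lines, the exosome to cell difference was present in each line. By the same fit, 6838 genes were higher and 4615 lower in OS-1, 5286 and 2194 in OS-2, 6287 and 3899 in OSCA-78, and 6005 and 3505 in OSCA-8. These balances moved with depth and with the scaling. With all libraries thinned to the smallest total they were 7153 and 2698 in OS-1, 2525 and 706 in OS-2, 6351 and 2234 in OSCA-78, and 5477 and 1772 in OSCA-8. With total counts they were 8515 and 2467 in OS-1, 4869 and 4245 in OS-2, 7606 and 2133 in OSCA-78 and 6750 and 2084 in OSCA-8, and with RLE scaling 7893 and 3234, 5658 and 1211, 7265 and 2600, and 6809 and 2228. The median log2 fold change of all genes in OS-2 was 0.14 with TMM, 0.56 with RLE and -0.37 with total counts. With TMM, 4247 genes passed as higher in each of the 4 lines and 1261 as lower in each. Another 120 genes passed in opposite directions in different lines. Genes scarce in cells could hardly pass as lower in any line, so the count of 4247 does not measure agreement between lines. The difference itself varied between lines for 1201 of 16211 genes (edgeR interaction test, adjusted p under 0.05). That count was 2052 without OS-1 cell replicate A, 349 without OS-2 cell replicate B, 408 without OS-2 exosome replicate 1 and 408 without OS-2 exosome replicate 2. It was 1962 with scaling to total counts, 2404 with DESeq2, and 495 with all libraries thinned to the smallest total, where the OS-2 count also fell from 7480 to 3231.

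The next comparison asked whether exosomes of the 5 lines differed from each other. They differed in 2283 of 15083 genes (edgeR, adjusted p under 0.05), and OS-2 stood furthest apart. Against the mean of the other lines, OS-2 exosomes had 1984 genes higher and 880 lower. Of the higher genes, 1547 belonged to group 5, the genes most abundant in cells. OSCA-32 exosomes had 385 genes higher and 437 lower, 353 of the latter in group 5. The numbers higher and lower were 2 and 35 in OS-1, 19 and 23 in OSCA-78, and 12 and 6 in OSCA-8. With total counts these numbers were 3933 and 247 in OSCA-32, 2627 and 32 in OS-1, 538 and 21 in OSCA-78, and 15 and 2 in OSCA-8. Of the group 5 genes, 637 were then higher and 200 lower in OSCA-32, with a median log2 fold change of 0.28 against -0.34 with TMM. The median log2 fold change of group 5 genes in OS-2 was 0.81 with TMM, 0.87 with RLE and 0.65 with upper quartile scaling but turned to -0.86 with total counts, under which 592 genes were higher and 10479 lower. Relative to the median of all genes, it was 1.01, 1.02, 1.01 and 0.99 under these scalings, a value that scaling could hardly move. The count over lines was 9510 with total counts, 1211 without OS-2 exosome replicate 1, 1121 without replicate 2, and 14 without the OS-2 line, an alternative chosen after seeing the data.

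Cells of the 4 lines differed from each other in 479 of 14148 genes (edgeR, adjusted p under 0.05), and in 1282 with the replicate letter as a block. Without the OS-2 line, an alternative chosen after seeing the data that leaves fewer samples, edgeR called 0 genes. Then 717 were at an unadjusted p under 0.05, and 3 were called with the block, 0 by limma and 216 by DESeq2. OS-2 cells had 979 genes higher and 1007 lower than the mean of the other lines, and 1476 and 1623 with the block. OSCA-78 cells had 26 higher and 8 lower, and 177 and 63 with the block. In OS-1 cells edgeR called 0 genes, with 1298 at an unadjusted p under 0.05, 2 with the block, 0 by limma and 296 by DESeq2. In OSCA-8 cells it called 0, with 1982 at an unadjusted p under 0.05, 64 with the block, 0 by limma and 567 by DESeq2. The count over lines moved with single libraries. It was 1045 and 590 without OS-1 replicates A and B, 62 and 0 without OS-2 replicates A and B, 9 and 0 without OSCA-78 replicates A and B, and 127 and 117 without OSCA-8 replicates A and B. With the replicate block, chosen for these counts after seeing the data, it was 1747 and 1096, 457 and 0, 391 and 412, and 310 and 257, in the same order. Where edgeR called 0, unadjusted p was under 0.05 for 1648 genes without OS-2 replicate B and 2598 without OSCA-78 replicate B, and DESeq2 called 1275 and 2269 genes, limma 0 and 159. Over all cell libraries DESeq2 called 2723 genes, and edgeR called 828 without a filter and 3141 with all 20 libraries in one fit.

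The last comparison asked whether the exosomes of a line carried the deviations of its own cells. Across 16211 genes, the deviation of each line from the mean of 4 lines was correlated between exosomes and cells. Genes are not independent replicates, so the test was over assignments of lines. Spearman's rho between matched lines was 0.28 for OS-2, 0.24 for OSCA-78, 0.24 for OSCA-8 and 0.05 for OS-1. The mean was 0.20 for matched and -0.06 for unmatched lines. The true assignment gave the highest mean of all 24 (exact one-sided permutation p = 0.0417, the smallest p possible), the next being 0.17. Exosomes correlated best with the cells of their own line in 3 of the 4 lines. Exosomes of OS-1 correlated more with the cells of OSCA-78 and OSCA-8 (0.12 each) than with their own. Without OS-1 cell replicate B the mean was 0.20 with an exact permutation p = 0.0833. Among 11591 genes tested in both fractions, the tests over lines called 99 genes in common where 75.6 would be shared by chance between independent lists. The genes higher in OS-2 shared 287 where chance gives 145.9, and those lower shared 119 where chance gives 40.8. The genes higher in OSCA-78 shared 0 where chance gives 0.0218, and those lower shared 3 where chance gives 0.0121. These chance values treat every gene as equally callable. Of the 1984 genes higher in OS-2 exosomes, 1547 were of group 5, so their overlap cannot be told apart from an effect of abundance. With total counts 592 genes were higher and 10479 lower in OS-2 exosomes.

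**Figure D4:**
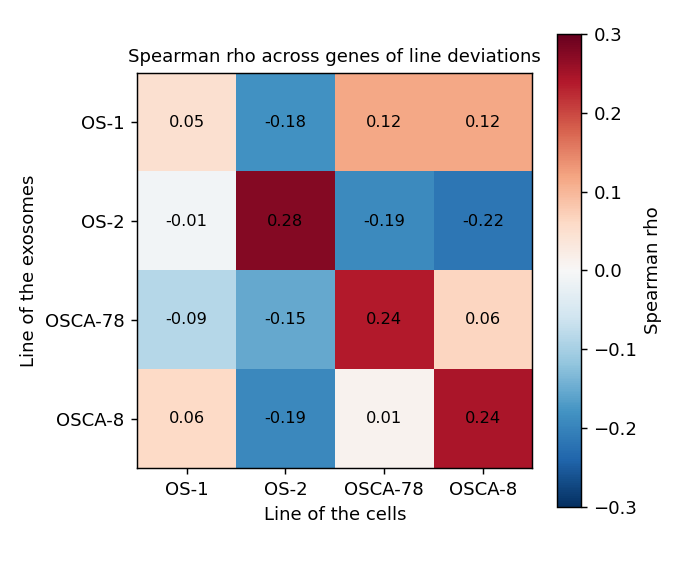
Spearman's rho across genes between the deviation of a line's exosomes (vertical axis) and of a line's cells (horizontal axis) from the mean of 4 lines, as a colour with the value in each square. The matched squares hold 0.28 for OS-2, 0.24 for OSCA-78, 0.24 for OSCA-8 and 0.05 for OS-1.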

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

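The test of fitted shares in this part was chosen after the result was seen. In OS-1, the group with enough libraries for a test of outliers, replicate 1 stood apart in ENSCAFG00000029369 with 19589 CPM, and replicate 2 stood apart in ENSCAFG00000015452 with 5.63 CPM, which is 2 counts. The limit used flags about 1 in 20 groups by chance for a single normally distributed measure. Here it was applied to many library measures and to the CPM of the named genes. A flag always arises where 1 library alone has a count, as for ENSCAFG00000015452, so the rate of chance flags is not known.

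The exosome to cell difference varied between lines for 1201 genes by the interaction test, and without OS-1 cell replicate A for 2052, without OS-2 cell replicate B for 349 and without either OS-2 exosome library for 408. Differences between lines may in part follow different proportions of cell-like and diffuse RNA. Each exosome library was fitted as a mixture of the pooled cell profile and the pooled OSCA-32 exosome profile, without the genes over 1% of any exosome library, and the cell profile took 62.2% and 65.1% in OS-2, 22.7% and 17.2% in OSCA-8, 12.5% and 2.28% in OSCA-78, and 12.5%, 11.4%, 0.976% and 0.405% in OS-1. With shares fitted on one part of the genes and libraries and directions read in the rest, 93.3% and 94.6% of the called genes between OS-2 exosomes and those of OS-1, OSCA-78 and OSCA-8 went the way the shares give, against 68.1% and 70.9% of all tested genes. The calls themselves used all libraries, which raises the former values. The shares are relative to OSCA-32, whose profile stood for diffuse RNA, so that any cell RNA in it would count as diffuse. The mean share of 0.0493% fitted to OSCA-32 itself is therefore built in. The test says only that OS-2 leans to the cell profile, and whether through the biology of the line or through its 2 exosome preparations stays open.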

How the results depend on the processing

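Chosen after seeing the data were the alternatives without the OS-2 line between lines, without the flattest exosome libraries, without genes over 1% of an exosome library, with the fitted cell share removed, and with the replicate block and 1 cell library left out; the others were chosen before the data were examined. The count for the mean of 4 lines stayed within 1.5 times of 12695 under all 37 alternatives, from 9522 against a fold of at least 2 to 14922 without a filter, and 11355 to 12679 with 1 library left out. The counts of single lines did so too, except OS-2 at 3231 after thinning to the lowest total. With 1 library left out they were 10478 to 11538 in OS-1, 5091 to 7664 in OS-2, 8388 to 10487 in OSCA-78 and 7347 to 9861 in OSCA-8. The interaction count of 1201 became 1962 with total counts, 495 after thinning, 2404 with DESeq2 and 742 without the 3 flattest exosome libraries of these lines, and 349 (without OS-2 cell replicate B) to 2052 (without OS-1 cell replicate A) with 1 library left out. Exosomes between lines went from 2283 to 9510 with total counts, 14 without OS-2, which leaves fewer samples, and 1121 (without OS-2 exosome replicate 2) to 2532 with 1 library left out. Cells between lines went from 479 to 828 without a filter, 2723 with DESeq2, 3141 with all 20 libraries in one fit, and 0 (without OS-2 replicate B) to 1045 (without OS-1 replicate A) with 1 library left out. Without the OS-2 line edgeR called 0, with 717 at an unadjusted p under 0.05, 3 with the replicate block, 0 by limma and 216 by DESeq2. Beyond fewer samples, the cause was not tested. With the replicate block, exosomes between lines gave 4080 and cells between lines 1282 (without OS-1 replicates A and B 1747 and 1096, OS-2 457 and 0, OSCA-78 391 and 412, OSCA-8 310 and 257), and of the counts named above no other moved by over 1.5 times. Cells of single lines moved too, as the report gives. The exosome numbers were not taken to pair the libraries, since 2 of 17 correlations of same-numbered deviations were over 0.1 (-0.05 to 0.32). Both were between OS-1 and OSCA-78, 0.316 for number 2 and 0.275 for number 3, so a pairing by number in these lines is not excluded. Lines with 2 libraries give mirrored deviations, so the 17 values are not all distinct. Under the block ENSCAFG00000029369 was no longer called, with a fitted log2 fold of 13.93 and an edgeR adjusted p of 1, and the cause was not tested. Its adjusted p ranged from 6.27e-05 to 0.0158 with 1 library left out. The line match lay between 0.170 and 0.209 with 1 library left out, with an exact permutation p = 0.0833 without OS-1 cell replicate B (0.199), and was 0.144 with the fitted cell share removed (exact permutation p = 0.0417). The gene list alternatives and the one without mitochondrial, ribosomal and small RNA genes were not run, since no gene could be named. In exosome libraries 4385 to 13299 genes reached 10 counts, against 11881 to 13475 in cells, the lowest 2 being those of OS-2, which were not the shallowest.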

Other observations

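The tests of line identity and of the replicate letters in this part were chosen after the result was seen. The most abundant exosome gene took 0.0274% to 32.3% of exosome counts and at most 0.0888% of cell counts, and 7 genes exceeded 1% of any exosome library. Replicates of OS-1 exosomes fell into pairs. The split of replicates 1 and 2 against 3 and 4 gave 1236 of 12460 genes by edgeR, and the other splits into pairs gave 0 and 0, with 77 and 63 genes at an unadjusted p under 0.05.

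The difference between exosomes and cells, 12695 genes, was not matched by other splits of the libraries within lines. Of 100 splits, the real one included, 1 gave as many genes, and the highest of the others gave 9908, with the labels of 2 libraries exchanged. Most of the other splits put cell and exosome libraries into the same group, which raises the estimated spread. The genes were also those kept under the real labels. Few calls from the other splits were therefore built in, so this test cannot measure chance.

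The exosome libraries detected more genes than cells at an equal total, while only 5 of them, OS-1 replicates 3 and 4, both of OSCA-32 and OSCA-78 replicate 3, had a smaller share in their 10 most abundant genes. Lower depth is argued against, since cells at the lowest total detected at most 11947 genes and exosomes at least 14883. Whether RNA of the line itself gives the breadth stays open. By best match, 4 libraries correlated better with exosomes of another line and 5 better with those of their own. Each did so by more than 2 standard errors, and 3 libraries lay within. The best match among other lines was picked from more libraries than that of the own line, which favours other lines. These errors are over genes, not replicates. A diffuse source common to all lines, such as genomic DNA, may contribute, but this stays open. In OSCA-32 exosomes set against cell libraries not used for the calls, 94.65% to 96.2% of called genes went the same way. Many called genes were scarce in all cell libraries and could hardly go another way, so these shares cannot decide. A shared selection of RNA into exosomes would also predict the same. Genomic DNA cannot be told apart from other sources, because 0 genes could be given a length.

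Cell libraries of one letter may share a preparation, since the A minus B difference correlated between every pair of lines, at 0.174 or more. Tested directly, 5 of 14148 genes differed between the letters by edgeR. The labels do not say what the letters stand for.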
